A study of Arabidopsis thaliana with 4 samples.

How the data were processed

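Total RNA of 7-day-old Arabidopsis thaliana seedlings held at 5 °C for 6 h was hybridised to 4 single-colour Affymetrix arrays. The arrays belong to 2 experiments, and in each a mutant line of SFR6 was treated in the cold beside wild-type Col-0. One experiment held sfr6-3 (WiscDsLox504A08) and the other sfr6-2 (SALK_048091), both insertion lines. Each line was measured once per experiment, so p-values measure only the spread between these arrays, pooled across genes.

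The deposited values are log2 expression values made by the authors with MAS5 from the Bioconductor package affy 1.36.1, per the submitters' processing notes. On the linear scale the mean of each array, trimmed by 2% at each end, was 500, so each array had been scaled on its own and no further normalization between arrays was applied here. Values ran from -4.34 to 15.21. Detection calls were not used here, and the number of arrays limits the precision of every value.

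The table held 22810 probe sets, of which 64 were array controls and were left out. The platform annotation paired 13513 probe sets with 1 gene, 503 with several genes, and did not name the other 8730. Names of 13436 of the single-gene probe sets were updated through the gene table of the TAIR10.1 assembly, and 77 kept the name of the annotation. The annotation paired 14.6% of protein-coding genes that have a symbol of their own and 63.1% of those known only by a locus tag. Well-studied genes are therefore thinly covered, and SFR6, CBF1, CBF2 and CBF3 have 0 single-gene probe sets. A gene with several single-gene probe sets, as 147 genes had, was represented by the one with the highest mean. Genes were kept when their mean log2 value reached the 40th percentile of the non-control probe sets, 6.46, which left 7204 of 13355 genes.

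Each mutant was set against the Col-0 array of its own experiment as a difference of log2 values, with 2-fold as the threshold and no test for a single pair. The combined effect was fitted with limma 3.58.1 in R 4.3.3, with experiment as a block and genotype as the term of interest, a variance trend on expression level, and Benjamini-Hochberg adjustment at 0.05. The 2 alleles counted as replicates of 1 mutant effect. This left 1 residual degree of freedom per gene, to which the empirical Bayes step added 17.5 prior degrees of freedom. Standard errors and p-values therefore rest mostly on variance pooled over genes, and little on the difference between a gene's own 2 ratios. The block comes from the design, which treated each mutant alongside its own wild type. Across genes, the difference between the experiments in Col-0 correlated with that in the mutants at 0.58, although the 2 differences share no array.

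Gene lists were tested with camera, with a preset correlation of 0.01 between genes and a variance trend, beside camera with an estimated correlation and fry. Medians were placed among 10000 random lists of the same size matched on expression in 20 bins. Before the data were examined, 19 lists of 302 gene entries were fixed, of which 30 were measured, meaning that they had a single-gene probe set and passed the filter. Because so few were, 22 family lists were added after the annotation had been read and before any expression difference was looked at. Lists with under 3 measured members were not tested, which left 25 tests, 4 of them on lists fixed at the start. At the first look at the lists camera was run without the variance trend. The trend was then added to match the limma fit, after those first p-values had been seen, and both versions are reported.

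The named genes follow a rule set before the data were examined. It takes the 12 lowest and the 12 highest genes by mean ratio among those at least 2-fold changed the same way in both experiments. It also takes the 5 lowest and the 5 highest for each allele and for the difference between alleles, and up to 4 members of each list with the largest absolute mean ratio. SFR6 and CBF1, CBF2 and CBF3, which the rule also names, have no value here.

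The fit was tested on simulated data for the combined effect over 7204 genes, with 200 genes changed. It called 54.5% of genes changed 2-fold and 99.0% of those changed 4-fold, and 3.75% of its calls were false. Without the block it made 0 calls on the same simulated values. For the list test, a simulated list of 20 shifted genes was called and 0 of 39 unshifted lists were. The simulated noise was independent between genes, with a variance set by expression level alone. The whole difference between the Col-0 arrays was put into both lines as the difference between experiments. These rates hold for that setting, and error rates under correlated genes or unequal variances were not simulated.

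Alternatives were quantile normalization, cyclic loess normalization, centring on the median, no filter, a filter at the 60th percentile, the 20th percentile added before taking logs, all probe sets, thresholds of 3-fold and 1.5-fold, no variance trend, no block, each array left out in turn, and the 2 other list tests. Mutants set against the Col-0 array of the other experiment, genotype labels exchanged within the sfr6-2 experiment, and camera without the variance trend were chosen after seeing the data. So was raising values under the filter level to that level, done for the ratios of the named genes and without a test. Promoter motifs were not analysed here, since a genome sequence was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.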

Results

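Expression was measured on 4 arrays, 1 for each of sfr6-3, sfr6-2 and the Col-0 seedlings treated beside each of them. SFR6 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and its mutants were first known for freezing sensitivity. The comparisons ask how transcript levels of cold-treated seedlings differ when SFR6 is disrupted. All 4 arrays had been brought to the same trimmed mean, and the median log2 value of the 7204 genes analysed lay between 8.49 and 8.58. No pair of arrays shared a value. SFR6 itself has 0 single-gene probe sets in the annotation, so the genotype labels could not be checked on the mutated gene.

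In sfr6-3, the lowest genes against its own Col-0 were AT1G19530 at a log2 ratio of -4.54, AT1G79660 at -3.33, AT1G68500 at -3.23, AT1G48100 at -3.15 and AT5G62360 at -3.11. The highest were AT5G12940 at 3.12, AT1G73600, of the phosphoethanolamine methyltransferase family, at 2.79, AT5G01870, of the lipid-transfer protein family, at 2.57, AT1G18980 at 2.48 and AT3G03060 at 2.29. Values under the filter level of 6.46 are dim, and ratios taken against them are inexact. With such values raised to 6.46 the ratio was -3.79 for AT1G19530, 1.78 for AT5G12940, 2.25 for AT1G18980 and 1.69 for AT3G03060, so that the order at either end is not settled. At least 2-fold lower were 277 genes and at least 2-fold higher 270. This comparison rests on 1 array per line and has no replicate check. The number of higher genes was 157 after cyclic loess normalization and 169 with the 20th percentile added before logs.

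In sfr6-2, the lowest genes against its own Col-0 were SAG29, a sugar transporter of the SWEET family, at a log2 ratio of -5.67, AT3G28220 at -4.31, AT1G48100 at -4.30, AT2G22590 at -3.77 and AT1G68500 at -3.68. The highest were AT3G02480 at 3.01, AT1G04560 at 2.98, M17, a late embryogenesis gene, at 2.81, AT3G01570, of the oleosin family of oil-body proteins, at 2.81 and AT1G73600 at 2.75. SAG29 read 3.28 in sfr6-2, under the filter level. With values raised to that level the ratio was -2.50 for SAG29, -2.27 for AT2G22590, 1.97 for AT1G04560, 0.73 for M17 and 1.82 for AT3G01570, so these ranks are not settled either. At least 2-fold lower were 258 genes and at least 2-fold higher 120. There was again 1 array per line. Against the Col-0 array of the other experiment, an alternative chosen after seeing the data, the counts were 567 and 473.

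Among genes past the filter and at least 2-fold changed in both alleles, more were lower than higher. SAG29 fell by 4.23 on the log2 scale (SE 0.45, limma adjusted p = 4.56e-06), AT1G48100 fell by 3.72 (SE 0.25, adjusted p = 3.69e-08) and AT3G28220 fell by 3.65 (SE 0.26, adjusted p = 4.05e-08). AT1G68500 fell by 3.45, AT1G16850 fell by 3.19, AT1G79660 fell by 3.08 and AT5G13200 fell by 3.08. AT5G33370 fell by 3.05, AT1G67865 fell by 2.92, AT3G17130 fell by 2.88, AT1G21790 fell by 2.57 and AT1G51090 fell by 2.53. AT1G73600 rose most, by 2.77 (SE 0.21, adjusted p = 8.17e-08), followed by AT5G01870 at 2.12 and AT3G15650 at 1.98. AT1G18980 rose by 1.84, AT2G43590, of the chitinase family, by 1.60, AT5G41670 by 1.55, AT1G47400 by 1.55, AT4G19380 by 1.53 and AT3G51330 by 1.49. AT2G31730 rose by 1.37, MED9, another Mediator subunit, by 1.35 (adjusted p = 0.0420), and UGT76B1, a glucosyltransferase acting in defence, with ratios of 1.18 in sfr6-3 and 1.53 in sfr6-2. With values under the filter level raised to it, the mean ratio was -2.65 for SAG29, -2.98 for AT1G16850, -1.85 for AT5G33370, 1.39 for AT3G15650, 1.73 for AT1G18980, 1.33 for AT3G51330, 0.99 for AT2G31730 and 0.81 for MED9. SAG29 therefore has no settled first rank. Leaving out 1 array, which also removes the block, moved some values by over 1.5 times. Without the sfr6-2 array SAG29 stood at -2.31, AT1G51090 at -3.87, AT3G15650 at 1.22 and AT2G43590 at 0.48, and without the sfr6-3 array AT1G51090 stood at -1.18, AT2G43590 at 2.72 and AT2G31730 at 0.75. Without Col-0 replicate 1, of the sfr6-3 experiment, AT1G18980 stood at 0.80, AT2G43590 at 0.29 and AT3G51330 at 0.76, and without Col-0 replicate 2 AT1G51090 stood at -1.50, AT1G18980 at 2.89, AT2G43590 at 2.92 and AT2G31730 at 0.74. The call of MED9 ended under all 3 other normalizations and without the filter, and that of AT2G31730 after median centring, after cyclic loess and without the filter. Those of AT3G15650 and AT3G51330 ended without the filter.

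**Figure D1:**
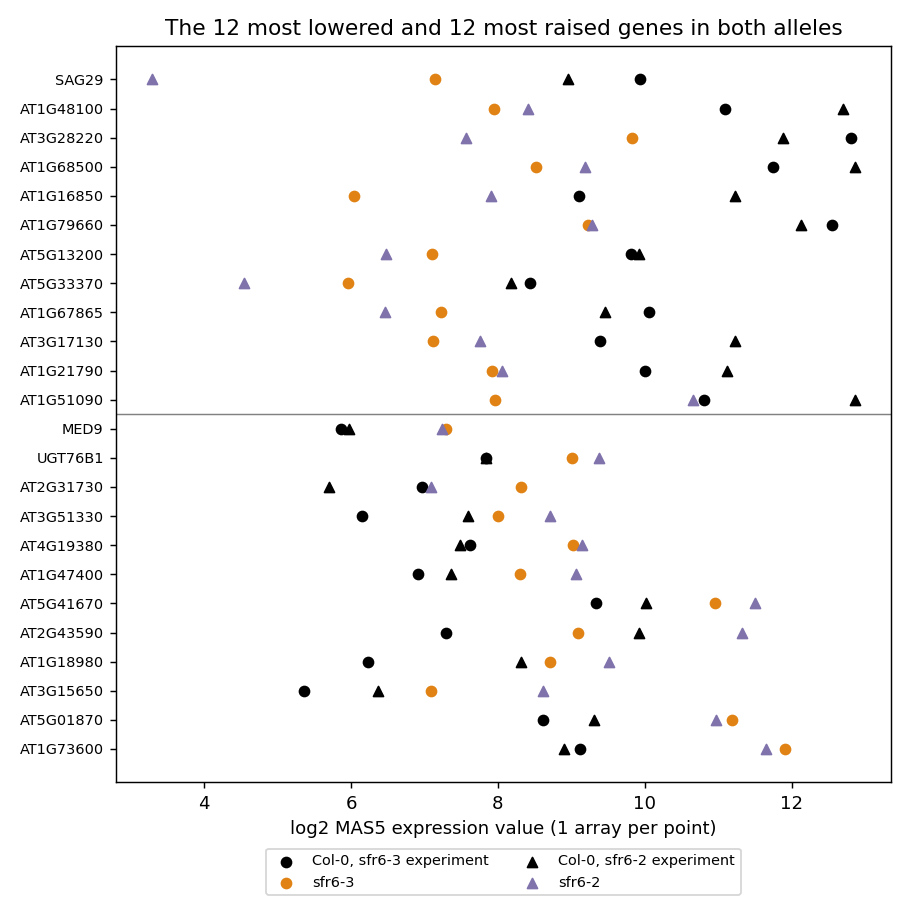
Log2 MAS5 expression value (horizontal axis) of the 12 most lowered and 12 most raised genes (vertical axis), with 1 point per array, circles for the sfr6-3 experiment, triangles for the sfr6-2 experiment, black for Col-0 and colour for the mutants. SAG29 reached the lowest value shown, 3.28 in sfr6-2. The genes were selected among those at least 2-fold changed the same way in both experiments, so their agreement follows from the selection.

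At least 2-fold lower in both experiments were 115 genes, against 9.92 for independent lists, and at least 2-fold higher in both were 21, against 4.50. The split depended on threshold and filter, with 264 lower and 187 higher at 1.5-fold, and 445 lower and 469 higher at 2-fold without the filter. The 2 comparisons share no control array. The log2 ratios of the alleles correlated across genes at a Pearson r of 0.43 and a Spearman rho of 0.31, a description, since genes are not independent replicates. limma with experiment as a block called 245 genes lower and 94 higher. The split was 210 to 35 after quantile normalization, 178 to 18 after cyclic loess and 181 to 18 after median centring. The median gene lay at 0.11 in sfr6-3 and at 0.08 in sfr6-2. Without the block limma called 0 genes, with 384 at an unadjusted p under 0.05 against 1214 with it, and leaving out any single array, which also removes the block, gave 0 calls.

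**Figure D2:**
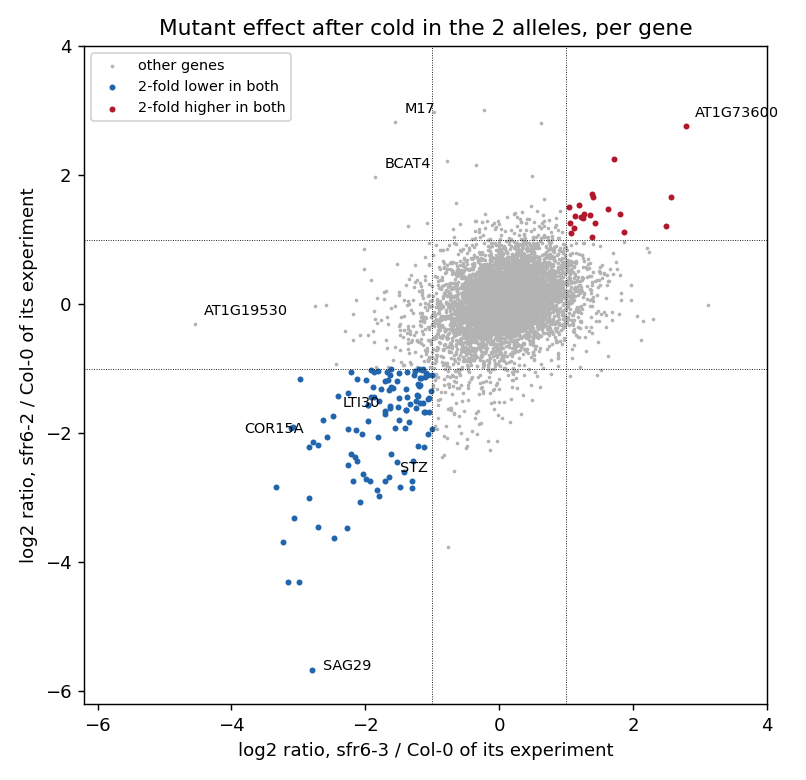
Log2 ratio of sfr6-3 over its Col-0 (horizontal axis) and of sfr6-2 over its Col-0 (vertical axis), with 1 point per gene and dotted lines at the 2-fold threshold. Past the filter, 115 genes were lower in both (blue) and 21 higher in both (red), against 445 and 469 without the filter, and M17 and BCAT4 lie on opposite sides in the 2 alleles.

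Cold-regulated genes under the CBF transcription factors fell in both mutants. All 4 arrays are of cold-treated seedlings, so a weaker response to cold and a lower level before it cannot be told apart. All 5 measured members of this list, of 28 listed, passed the limma test: COR15A, a chloroplast protein that protects membranes during freezing, fell by 2.46 (SE 0.20, adjusted p = 2.71e-07), the dehydrin gene LTI30 fell with ratios of -2.48 in sfr6-3 and -1.73 in sfr6-2, COR15B fell by 1.32 and TIL, a lipocalin gene, fell by 0.91. The same 5 passed when adjusted over the list alone. The list median was -1.66 in sfr6-3 and -1.26 in sfr6-2, while the 2 Col-0 arrays differed by 0.40. Against other genes the list stood lower with camera (adjusted p = 5.36e-12). The call was lost with an estimated correlation (adjusted p = 0.82). The estimate was -0.2, under the preset 0.01, so correlation between the members is not what ended the call. That version of camera rests on 1 residual degree of freedom and called 0 of the 25 lists. It therefore decides nothing for or against a list, here or below. With fry, which tests whether the list itself moves one way and not whether it differs from other genes, the adjusted p = 0.466. The reference genes had the same value with fry, so it does not set the list apart from them in either sense. The call of TIL ended under several alternatives, among them quantile normalization, and that of COR15B without the filter. COR15B stood at -0.86 without the sfr6-3 array. Of the early cold transcription factors, STZ, a zinc-finger repressor gene, was the 1 measured member of 17 and fell by 1.97 (SE 0.24, adjusted p = 2.59e-05).

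Of 10 measured late embryogenesis abundant and dehydrin genes, which protect cells during water loss, 5 fell, 0 rose and 5 did not pass the test. The 5 are 4 genes of the CBF list and LEA4-5, which fell by 1.68 (adjusted p = 0.000264). LEA4-5 stood at -2.54 without Col-0 replicate 1, -0.58 without sfr6-3, -0.82 without Col-0 replicate 2 and -2.78 without sfr6-2. The mean ratios of AT2G44060 at 0.51, AtLEA4-1 at 0.47, AT2G46140 at 0.37 and LEA18 at 0.15 lay above 0. Such a mean can hide opposite directions, as for AtLEA4-1 at -0.35 in sfr6-3 and 1.29 in sfr6-2, and LEA18 at -0.64 and 0.94. Adjusted over the list alone AT2G44060 passed as higher and AT1G54410, at -0.66, as lower. The list median was -0.66 in sfr6-3 and -0.83 in sfr6-2 (camera adjusted p = 4.67e-06), and the adjusted p = 0.82 with an estimated correlation. Between the Col-0 arrays it was 0.30. With fry, which makes no comparison with other genes, the adjusted p = 0.466. The 4 genes shared with the CBF list enter the median and the camera call, which is thus not separate from that of the CBF list. The list without them was not tested. Its genes are LEA4-5 and AT1G54410, below 0, and those named above with mean ratios above 0. The camera call also ended without the sfr6-3 array (adjusted p = 0.156) and without the Col-0 array of the sfr6-2 experiment (adjusted p = 0.0854).

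Genes encoded in the chloroplast were lower as a list, with small shifts, the larger in sfr6-3, a difference that was not tested. Of 68 measured genes, 4 fell, petL by 0.96 on the log2 scale, psbE by 0.87 and psbA by 0.74, which encode parts of the photosynthetic electron transport chain, and psbB, outside the naming rule and chosen after its value was seen, by 0.69. The calls of petL and psbA ended after median centring and after cyclic loess, and that of psbE without the filter, and petL stood at -0.50 without the sfr6-3 array. The other 64 did not pass the test, among them ndhE at -0.74. The list median was -0.37 in sfr6-3 and -0.07 in sfr6-2 (camera adjusted p = 7.50e-06), and 0.82 was the adjusted p with an estimated correlation. Between the Col-0 arrays the list median was -0.03, at percentile 0.16 of random lists, against percentile 2.3 for sfr6-2, so a shift of the size in sfr6-2 is not set apart from that between wild-type arrays. The probe set for 25S ribosomal RNA read 13.65 in Col-0 and 13.38 in sfr6-3, and 13.94 in Col-0 and 13.91 in sfr6-2. Of 22 nuclear photosynthesis genes 0 passed the limma test, and the list stood at -0.37 and -0.13 (camera adjusted p = 0.00269), and the adjusted p = 0.82 with an estimated correlation. Between the Col-0 arrays its median differed by 0.20. The largest values were NdhS at -0.68, LHCB4.2 at -0.62, LHCB4.3 at -0.52 and PRK at -0.47. The call was also lost after quantile normalization (adjusted p = 0.0979), and without the Col-0 array of the sfr6-2 experiment (median -0.15, adjusted p = 0.200). Without the sfr6-2 array its median was -0.40, without the sfr6-3 array it turned to 0.05, and the chloroplast list no longer passed (adjusted p = 0.0538). In the photosynthesis list fixed at the start, LHCB4.1 at -0.04 and RCA at -0.02 did not pass, and both turned above 0 after quantile and cyclic loess normalization.

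**Figure D3:**
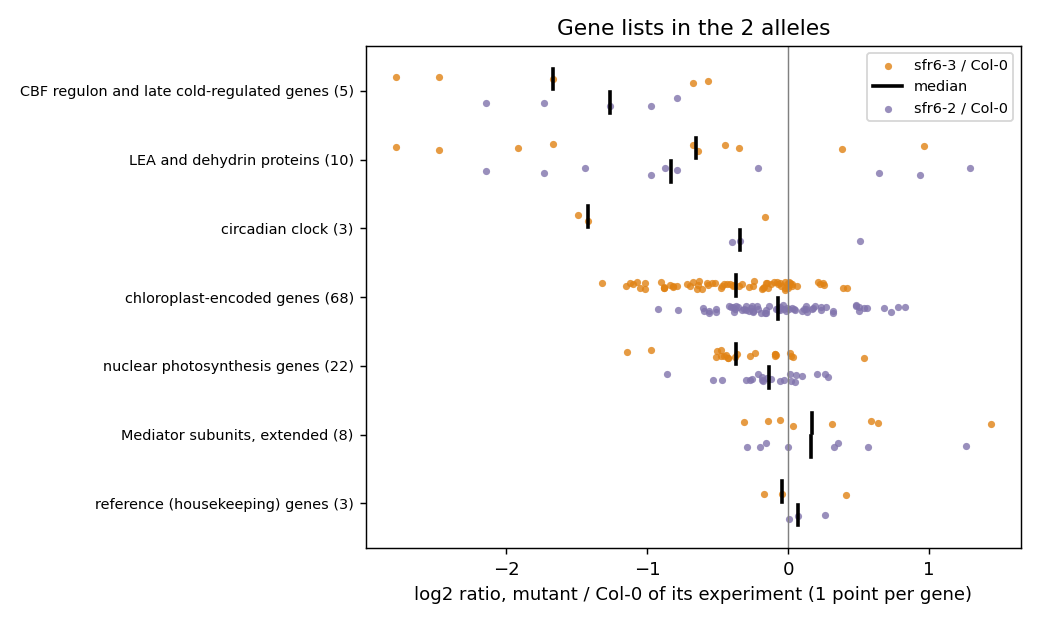
Log2 ratio of each mutant over the Col-0 of its experiment (horizontal axis) for 7 gene lists (vertical axis, number of measured genes in parentheses), with 1 point per gene, orange for sfr6-3, purple for sfr6-2 and a black bar at the list median. All 5 genes of the list of CBF regulon and late cold-regulated genes lie below 0 in both alleles, while the reference genes lie around 0.

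Of the clock genes, COR27 fell by 0.92 (adjusted p = 0.0351) and AT4G33980 fell by 0.91 (adjusted p = 0.0361), both with the larger ratio in sfr6-3, at -1.49 and -1.42. GI, which acts in the clock and in flowering, stood at 0.17 and did not pass. The list as a whole did not pass camera (adjusted p = 0.0666). The calls of COR27 and AT4G33980 ended under all 3 other normalizations. They stood at -0.27 and -0.31 without the sfr6-3 array, and at -1.56 and -1.50 without the sfr6-2 array.

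Among defence genes, PDF1.2, a defensin gene induced by jasmonate and ethylene, fell by 1.65 (SE 0.33, adjusted p = 0.00483), the 1 measured member of its list. In the defensin and thionin list, THI2.2 fell by 1.04 (adjusted p = 0.00284), and PDF2.1 at 0.60 and PDF2.5 at 0.45 did not pass. The list of 6 did not pass camera (adjusted p = 0.292), and the calls of PDF1.2 and THI2.2 ended without the filter. Of 4 jasmonate genes 1 fell, PDF1.2 again, and OPCL1 at -0.68, MYC4 at 0.19 and MYC3 at 0.16 did not pass (list adjusted p = 0.178). Of 2 measured iron-deficiency genes, AT3G13610, which acts in coumarin synthesis, rose by 0.87 (adjusted p = 0.0208) and PYE stood at 0.22. The call of AT3G13610 ended after median centring and after cyclic loess.

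UDP-glycosyltransferase and expansin genes moved in both directions, and the beta-glucosidases that passed fell. Of 29 UDP-glycosyltransferases, UGT72B3 fell by 1.76 (adjusted p = 6.31e-05), while UGT76B1, UGT78D1, which acts on flavonols, and UGT85A2 rose, the last 2 by 1.09 and 0.88. EXLA2 fell by 1.39 and EXPA4 rose by 1.33, the 2 of 17 expansin and xyloglucan endotransglucosylase genes that passed, and XTH19 stood at 0.94 and EXPA8 at -0.60. Leaving out each array in turn, XTH19 ranged from 0.0058 to 1.88 and EXPA8 from -1.13 to -0.069. Of 10 beta-glucosidases BGLU46 fell by 2.02 and BGLU25 fell by 1.12, with BGLU16 at 0.47 and BGLU44 at 0.37. Of 8 glutathione S-transferases GSTU22 rose by 0.85 and GSTU20 stood at 0.73, and of 7 U-box ligases PUB19 fell by 1.34. Adjusted over the list alone UGT73B4 at 0.88 and GSTU20 passed too, giving 1 lower and 4 higher UDP-glycosyltransferases and 0 lower and 2 higher glutathione S-transferases. None of these 5 lists passed camera, with adjusted p = 0.344 for the UDP-glycosyltransferases, 0.978 for the expansins, 0.334 for the beta-glucosidases, 0.344 for the glutathione S-transferases and 0.319 for the U-box ligases. The calls of UGT85A2, GSTU22 and PUB19 ended after median centring and after cyclic loess, and those of BGLU46 and BGLU25 without the filter. Without Col-0 replicate 1 GSTU22 stood at 0.22 and BGLU25 at -1.85, and without Col-0 replicate 2 GSTU22 stood at 1.49, BGLU25 at -0.39 and PUB19 at -0.72. Without the sfr6-3 array the values were 1.31 for GSTU22, -3.21 for BGLU46 and -0.63 for BGLU25, and without the sfr6-2 array 0.39 for GSTU22 and -0.83 for BGLU46. With values under the filter level raised to it BGLU46 stood at -1.40.

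In the other tested lists 0 members fell when adjusted over all genes, and the genes that rose were MED9 of 8 Mediator subunits and UGT78D1 of 4 flavonoid genes. The Mediator list fixed at the start had 5 measured members, with AT2G22370 at 0.58, AT5G20170 at 0.33, AT5G48630 at -0.30 and MED6 at 0.18 (list adjusted p = 0.919), and its extension did not pass (adjusted p = 0.499). Of 7 SWEET transporters on the list, which did not hold SAG29, 0 passed, with SWEET4 at -0.99, and the list's adjusted p = 0.0617, which was 0.0495 without the variance trend. The 9 ATG8 autophagy genes, with ATG8F at -0.67, did not pass as a list (adjusted p = 0.0760), nor did the 7 tubulins, with TUB1 at 0.60 and TUB6 at 0.40 (adjusted p = 0.114). The adjusted p = 0.344 for the flavonoid genes and for the CYP71B cytochromes, where CYP71B5 stood at -0.80. The adjusted p = 0.499 for mitochondrion-encoded genes, with cox1 at -0.61, and 0.800 for the family 9 endoglucanases, with GH9B13 at 0.80, and for the trichome birefringence-like genes, with TBL39 at 0.69. The adjusted p = 0.978 for auxin genes, with YUC2 at 0.66, and 0.918 for RALF-like peptides, with RALFL32 at -0.73. Adjusted over the list alone, ATG8F, CYP71B5 and RALFL32 passed as lower, each the 1 gene of its list. The 3 reference genes, AT2G28390 at 0.21, AT4G34270 at 0.04 and PEX4 at 0.02, did not pass (list adjusted p = 0.919), and the last 2 turned below 0 after median centring.

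Some lists held 1 or 2 measured genes, none of which passed over all genes. These were DFR at 0.11 and UGT78D2 at 0.39 for flavonoid synthesis, BCAT4 at 0.06 for glucosinolate synthesis, DPE1 at 0.68 for starch metabolism, and EXPA8 at -0.60 and COB at -0.48 for wall expansion. Adjusted over the list alone DPE1 passed as higher, being the 1 gene measured, so that this is its unadjusted p of 0.0277. The root markers EXPA7 at -0.36 and PYK10 at -0.27, and the calcium sensor CML42 at -0.10, did not pass either. The lists for flowering time, abscisic acid and dehydration, sugar starvation, and seed storage held 0 genes with a single-gene probe set. The 3 such genes for salicylic acid defence and the 1 for heat shock were below the filter.

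The alleles differed most at M17, where the sfr6-3 ratio minus the sfr6-2 ratio was -4.37, at AT1G19530 with -4.23, at AT1G04560 with -3.95, at BCAT4, an enzyme gene of glucosinolate synthesis, with -3.82, and at AT3G02480 with -3.23. In the other direction stood AT5G12940 at 3.14, AT2G22590 at 3.01, SAG29 at 2.88, AT5G10130 at 2.66 and AT5G62340 at 2.56. With values under the filter level raised to it the difference was -2.28 for M17, -3.49 for AT1G19530, -2.30 for AT1G04560, -3.34 for BCAT4, 1.79 for AT5G12940, 1.71 for AT2G22590, -0.30 for SAG29 and 1.26 for AT5G10130, so the ranks are not settled. These differences have no residual degrees of freedom and were not tested.

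The 2 Col-0 arrays lay further apart than either mutant from its own wild type. GI was at 8.45 in Col-0 of the sfr6-3 experiment and at 11.45 in that of the sfr6-2 experiment, and the mutants beside them were at 8.29 and 11.96. M17 was at 8.33 and 4.38, and BCAT4 at 9.57 and 5.98, in the same order. Between the Col-0 arrays, 404 genes were at least 2-fold lower and 339 at least 2-fold higher in the sfr6-2 experiment. That is 743 genes, against 547 for sfr6-3 and 378 for sfr6-2 against their own Col-0.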

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

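The scaling, intensity and dim-gene tests of the excess of lowered genes were chosen only after their results were seen, as were the tests of a low Col-0 array on the named seed genes. The tests on unseen seed genes were set before theirs, and the reading of the one on Col-0 was changed afterwards.

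Of the named genes, 3 were 2-fold changed in opposite directions in the 2 alleles, and these differences were not tested. For M17 the sfr6-3 ratio minus the sfr6-2 ratio was -4.37, for BCAT4 it was -3.82, and for AT5G62340 it was 2.56. With values under the filter level raised to it, M17 stood at 0.73 in sfr6-2, which is under 2-fold. Probe sets without a single named gene are outside the comparisons. Of 6368 past the filter, 107 were at least 2-fold lower in both alleles against 10.2 for independent lists, and 35 were at least 2-fold higher in both against 4.73.

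M17, AT1G04560, AT3G02480 and AT3G01570, known from seeds and embryos, were the highest genes of sfr6-2 beside AT1G73600, with levels of 7.19, 8.43, 10.40 and 8.28 there. Some late or ungerminated seedlings in that sample are a candidate explanation, which predicts that other seed and early-seedling genes were high too. A list of 40 was written after those genes were seen. Apart from listed genes already named, 3 of its genes were measured, AtLEA4-1, LEA18 and BGLU19. AtLEA4-1 and LEA18 also belong to the late embryogenesis list, computed earlier, so this is not a test on wholly unseen values. The median sfr6-2 ratio of the 3 genes, 0.94, lay at percentile 99.66 of random lists, against 10.88 for sfr6-3. Of listed genes left out as seen earlier, ICL stood at 2.16 and LEA4-5 at -1.44 in sfr6-2. A low Col-0 array cannot be told apart for the 4 named genes, since against the other Col-0 array M17 was at -1.14 and the median of AT1G04560, AT3G02480 and AT3G01570, 2.06, is of genes picked as highest on the same sfr6-2 array. In that test, which had been set to exclude a low Col-0 array, AtLEA4-1, LEA18 and BGLU19 had a median of 0.99. Their Col-0 levels were not low (median difference 0.25) and M17 goes the other way. Those 3 genes therefore do not decide it for the named genes. With 1 array per line a stage difference between the plates and an effect of the allele both stay open.

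Among genes 2-fold changed in both alleles, 84.6% were lower. A shift of 0.2 added to both alleles would bring the share to 60%, so array scaling as the whole cause needs a median gene near -0.2, and it is argued against by medians of 0.107 in sfr6-3 and 0.082 in sfr6-2, taking most genes as unchanged. An intensity-dependent bias is argued against in the same way by medians of 0.090 and 0.074 at the expression levels of the genes lower in both. Noise of dim genes as the cause is argued against by 88.0% with the stricter filter, although with no filter the share was 48.7%. At 1.5-fold 264 were lower and 187 higher in both, while more were higher than lower in each allele, 1067 to 698 in sfr6-3 and 666 to 609 in sfr6-2, so whether loss of SFR6 function lowers more genes than it raises stays open.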

How the results depend on the processing

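The crossed controls, the exchanged labels and camera without the variance trend were chosen after seeing the data. Unless a value below gives the reason, the cause was not tested. The correlation between alleles kept its sign under all alternatives run on it and fell to 0.10 without the filter. Counts of genes are given as lower and higher in sfr6-3, in sfr6-2, in both, and between the Col-0 arrays. They were 277 and 270, 258 and 120, 115 and 21, and 404 and 339 as reported. They were 97 and 36, 100 and 14, 40 and 3, and 147 and 104 at 3-fold, 698 and 1067, 609 and 666, 264 and 187, and 892 and 990 at 1.5-fold, 1531 and 1708, 1434 and 1701, 445 and 469, and 1869 and 1647 without the filter, 180 and 112, 169 and 37, 88 and 12, and 257 and 160 with the filter at the 60th percentile, and 552 and 523, 499 and 241, 222 and 56, and 770 and 634 over all probe sets, where the thresholds and the number of genes entered account for the direction of the move. The sfr6-3 higher count was 157 after cyclic loess and 169 with the 20th percentile added. With crossed controls sfr6-2 gave 567 and 473, and both gave 71 and 9, of which 60 and 8 were among the genes reported.

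The limma calls lower and higher were 245 and 94 as reported, and the higher calls were 35 after quantile normalization, 18 after cyclic loess, 18 after median centring and 40 with the 20th percentile added. They were 101 and 13 without the filter, 136 and 14 with the filter at the 60th percentile, 140 and 30 without the variance trend, and 401 lower over all probe sets. Of the calls after quantile normalization 243 of 245 were among those reported, and 196 of 196 after cyclic loess. With no replicate block there were 0 lower and 0 higher calls in limma, with 384 genes at an unadjusted p under 0.05 and 0.164 as the smallest adjusted p. The simulated data also gave 0 calls without the block. There the whole Col-0 difference was shared by both lines, while in the data the 2 differences correlated at 0.58. The simulation therefore cannot tell what the 0 calls without the block mean for the reported calls. Leaving out each array in turn, without the block, gave 0 to 0 calls in each direction. With the labels exchanged within the sfr6-2 experiment limma called 0 genes, with 57 at an unadjusted p under 0.05. This exchange moves any effect shared by the alleles into the residual, so its 0 calls say nothing for the reported calls. Groups of 2 arrays or fewer allow no count of other splits.

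The CBF regulon list was run under the 3 other normalizations, without the filter, with the stricter filter, with the 20th percentile added, without the block, with each array left out, with an estimated correlation, with fry and without the variance trend in camera. In these its median stayed at or below -1.02. It passed in all but the estimated correlation and fry, where the median was -1.32 and the adjusted p = 0.82 and 0.466, and fry makes no comparison with other genes. It was not run over all probe sets, with crossed controls, with exchanged labels, at other fold thresholds or without the intensity trend of limma. The estimated correlation and fry called 0 of the 25 lists. Both rest on 1 residual degree of freedom, and their power was not measured, so their 0 calls decide nothing for or against a list. With fry the reference genes had the same adjusted p as the CBF list, 0.466. Without the variance trend 5 lists passed in place of 4, the added one being the SWEET transporters. Lists that came to pass in other settings were the SWEET transporters, ATG8 genes and tubulins after cyclic loess, the SWEET transporters after median centring, clock, jasmonate, ATG8 and tubulin genes without the filter, and ATG8 genes without the block. With an array left out, clock genes and defensins came to pass without Col-0 replicate 1 or sfr6-2, SWEET transporters without sfr6-3 or Col-0 replicate 2, and U-box ligases without sfr6-3. All sign changes below are of values that had not passed limma, or of list medians, of which the nuclear photosynthesis genes alone had passed camera. After quantile normalization the mean ratio turned sign for LHCB4.1 (0.095), RCA (0.12), BCAT4 (-0.0067), AT4G34270 (-0.025), the list of defensins and thionins (0.043), the list of expansins and xyloglucan endotransglucosylases (-0.061), the list of beta-glucosidases (-0.054). After cyclic loess normalization the mean ratio turned sign for LHCB4.1 (0.024), RCA (0.059), DFR (-0.031), BCAT4 (-0.067), AT4G34270 (-0.059), PEX4 (-0.048), the list of reference (housekeeping) genes (-0.048), the list of expansins and xyloglucan endotransglucosylases (-0.11), the list of beta-glucosidases (-0.093). After median centring the mean ratio turned sign for BCAT4 (-0.0041), AT4G34270 (-0.020), PEX4 (-0.049), the list of reference (housekeeping) genes (-0.020), the list of expansins and xyloglucan endotransglucosylases (-0.054), the list of beta-glucosidases (-0.028). Without the filter the mean ratio turned sign for the list of expansins and xyloglucan endotransglucosylases (-0.033). With the filter at the 60th percentile the mean ratio turned sign for the list of Mediator subunits (-0.17), the list of trichome birefringence-like wall acetylation (-0.016), the list of auxin synthesis, conjugation and response (-0.046), the list of Mediator subunits, extended (-0.028). With the 20th percentile added before logs the mean ratio turned sign for BCAT4 (-0.052). Leaving out each array in turn, the range was -1.66 to 2.01 for GI, -0.16 to 0.60 for PYE, -0.13 to 0.16 for PEX4, -0.78 to 0.11 for nad4, -0.25 to 1.46 for PDF2.1, -0.62 to 1.58 for GSTU25, -0.99 to 0.22 for GSTU16, -0.49 to 0.29 for CYP71B26. It was -1.13 to 0.22 for SWEET16, -1.01 to 0.43 for SWEET2, -1.10 to 1.43 for GH9C2, -0.60 to 0.21 for GH3.17, -0.079 to 1.28 for TUB1, -0.33 to 0.25 for LHCB4.1, -0.12 to 0.083 for RCA, -0.24 to 0.46 for DFR. It was -1.16 to 0.43 for EXPA7, -0.70 to 0.15 for PYK10, -0.48 to 0.89 for ccb452, -1.36 to 0.12 for LHCB4.2, -1.14 to 0.087 for LHCB4.3, -0.16 to 0.48 for MYC3, -0.18 to 0.66 for GH3.3, -0.57 to 0.37 for CML42. It was -0.40 to 1.15 for RALFL33, -1.74 to 1.86 for BCAT4, -0.089 to 0.44 for MED6, -0.12 to 0.21 for AT4G34270, -0.85 to 0.27 for GH9C1, -0.16 to 0.69 for ccb382, -0.56 to 0.13 for CHIL, -1.04 to 0.20 for PUB22. It was -0.79 to 0.32 for PUB23. For lists the median ranged from -0.48 to 0.11 for mitochondrion-encoded genes, -0.30 to 0.20 for CYP71B cytochrome P450s, -0.63 to 0.12 for SWEET sugar transporters, -0.28 to 0.44 for expansins and xyloglucan endotransglucosylases, -0.65 to 0.67 for glycosyl hydrolase family 9 (endoglucanases). It ranged from -0.40 to 0.047 for nuclear photosynthesis genes, -0.023 to 0.52 for flavonoid glycosylation and late anthocyanin genes, -0.44 to 0.38 for defensins and thionins, -0.38 to 0.58 for auxin synthesis, conjugation and response, -0.017 to 0.28 for Mediator subunits, extended. It ranged from -0.069 to 0.52 for RALF-like peptides, -0.089 to 0.28 for Mediator subunits, -0.0078 to 0.11 for reference (housekeeping) genes, -0.060 to 0.16 for beta-glucosidases, -0.64 to 0.32 for plant U-box ubiquitin ligases. Promoter motifs and their 3 alternatives were not run, since a genome sequence was not used here.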

Other observations

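The tests of the distance between experiments were chosen only after their results were seen, and the iron-gene test was set before its result.

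Between the 2 Col-0 arrays, 6 of the 25 tested lists had a median in the outer 1% of random lists at either end, a limit chosen after the values were seen. The 17 expansin and xyloglucan endotransglucosylase genes had a median log2 difference of 0.61, higher in the sfr6-2 experiment, at percentile 100 of random lists. The 5 family 9 endoglucanases stood at 1.13 (percentile 99.9) and the 6 defensins and thionins at 0.82 (percentile 99.95), while the 7 CYP71B cytochromes stood at -0.57 (percentile 0.55), the 29 UDP-glycosyltransferases at -0.21 (percentile 0.805) and the 68 chloroplast-encoded genes at -0.03 (percentile 0.16). These values compare 1 array with 1 other.

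The Col-0 arrays differed 2-fold in 743 genes, and the mutant arrays in 631. A difference between the experiments shared by both lines, such as the hour or stage of harvest, is a candidate explanation, and the 2 differences, which share no array, correlated across genes at 0.58. GI, whose transcript follows the time of day, moved alike in Col-0 and mutants, with 3.00 between the Col-0 arrays. The other measured clock genes, COR27 and AT4G33980, differed by 0.14 and 0.17 between the Col-0 arrays. These 3 genes decide nothing about the hour. Unequal RNA degradation cannot be told apart, because the largest shift in the 3' minus 5' value of a control transcript between the Col-0 arrays was -0.44, for ubiquitin, while GAPDH shifted by -0.07 and actin by 0.21. Against its own Col-0, ubiquitin shifted by 0.44 in sfr6-2 and 0.16 in sfr6-3, and actin by -0.18 in sfr6-2 and -0.06 in sfr6-3, so the same holds for the mutant comparisons.

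AT1G47400 and AT3G13610, both known to be induced by iron deficiency, rose in both alleles. A wider iron-deficiency response is a possible explanation, tested on 8 other such genes measured from a list of 25. Their median mean ratio was 0.23, at percentile 84.2 of random lists, and 0 of the 8 passed the limma test. The prediction set beforehand, of a higher percentile, was not met. With 8 of 25 genes measured, of which 6 were higher in sfr6-2 and 4 in both alleles, a wider response is not excluded. AT3G56360 had the highest mean ratio of the 8, 0.70.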
